A study of Mus musculus with 23 samples.

How the data were processed

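Gene expression was measured by RNA sequencing in 23 mouse libraries in 8 groups. Per the labels, total RNA was depleted of ribosomal RNA and sequenced from both ends on an Illumina HiSeq instrument. The authors deposited 2 tables of raw counts per gene, with no normalization, and the unit of every value used is a deposited raw count. The submitters' processing notes name Trimmomatic 0.32, STAR 2.3.0e, featureCounts 1.4.4, SAMtools 0.1.19, GATK, Picard and the mm10 build, without saying what each was used for. They do not state the annotation release, the strand setting or the handling of reads with several matches.

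The earlier table held 21 columns and the later one 22, over the same 39017 genes. For 12 libraries present in both, the values were identical. The later table supplied 22 libraries, and the earlier one supplied the single K27M-P tumour library. The 8 other columns of the earlier table name samples outside this set and were not analysed here. Columns were matched to samples by title. For 9 titles the listed variant file carries the name of another sample, and these variant files were not analysed here. The design text gives 16 preneoplastic and 5 tumour samples, whereas 15 and 8 libraries were held. Rows were kept by Ensembl identifier, since 162 symbols occur on more than 1 row. Coordinates are from GENCODE M21 on GRCm38, to which 37693 of the identifiers could be matched.

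Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Libraries were scaled by the trimmed mean of M-values (TMM), and levels are given as CPM, counts relative to the scaled library total, mean ± SD over libraries. Genes with low counts were removed with filterByExpr, using a minimum count of 10 and a minimum total of 15. A quasi-likelihood F-test was fitted to group means, and p-values were adjusted by the Benjamini-Hochberg method over all genes tested. A gene was called at an adjusted p below 0.05. One fit held the 15 preneoplastic libraries, with 20197 genes and 10 residual degrees of freedom. The other held the 13 libraries of K27M-AP, K27M-APP and their tumours, with 20373 genes and 9 residual degrees of freedom. The coefficient of variation between replicates was 0.399 in the first and 0.475 in the second. There were 8 comparisons of groups, and 2 interaction terms that asked whether an effect differed between backgrounds.

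Before the data were examined, 22 gene lists were written. They covered p53 target genes, proliferation, cell cycle inhibitors, receptor tyrosine kinase and MAPK response, interferon response, MHC class I and II, hypoxia and glycolysis, imprinted genes, sex-linked genes, Hox genes, polycomb-regulated developmental regulators and the polycomb complexes. The other lists were markers of neural stem and progenitor cells, oligodendrocyte precursor cells, mature oligodendrocytes, astrocytes, neurons, microglia and macrophages, endothelial cells and pericytes, fibroblasts and extracellular matrix, lymphocytes, and red blood cells. Each list was tested with limma's camera on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, adjusted over the lists of a comparison. The test was repeated with an estimated correlation. Members past the threshold were counted from the edgeR fit, over all genes and adjusted over the list alone.

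The rule for naming genes was fixed at the same time. Pdgfra, Trp53, Atrx, H3f3a and H3f3b are given everywhere. In each comparison the 6 largest rises and 6 largest falls are named among called genes with a mean of at least 10 CPM in a group and no overlap between libraries, leaving out predicted genes and sex-linked genes. For each list, up to 2 members that rose and 2 that fell are named by smallest adjusted p, or else the member with the highest mean, as values only. For interactions up to 4 genes a direction could be named, and none was called. Other members of lists given as examples, among them those past the threshold over the list alone, were chosen after their values were seen. Some genes that the rule names, and 1 list result that rests on a single such gene, are not reported here.

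Alternatives planned before the data were examined were DESeq2 size factors, no filter on low counts, DESeq2 1.42.0 as the test, the replicate number as a block, all 23 libraries in the fit, only the compared groups in the fit, and leaving out each library in turn. For the lists, size factors, the estimated correlation and the replicate block were planned. Ranges of a list's adjusted p over the alternatives are for the preset correlation. They leave out the estimated one, whose value is given beside each list. Chosen after the data were seen were a term for the table in which a library first appears, each table's libraries alone, and limma's voom with sample weights. List tests with the table term, with each table's libraries alone and with each library left out were added then too, as was the replicate block for K27M-APP against EV-PDGFRA. Of the 23 libraries, 13 are in the earlier table and 10 in the later table alone. The labels name no batch, and this division is called the table batch.

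The procedure was tested on simulated data with the same group sizes, in which 200 genes were changed. In 6 comparisons, edgeR recovered 58 to 90% of genes changed by a fold of 4. False calls were 0.763 to 4.41% of edgeR's calls, 20.3 to 30% of those of DESeq2 and 1.52 to 5.59% of those of voom with weights. A planted shift of the p53 list was found in all 6, with 0 other lists called. The simulated genes varied independently, without a batch or an odd library. The simulation therefore cannot show how often the preset correlation calls a list falsely when its genes vary together.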

Results

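RNA was measured in mouse cells that had received genes by electroporation of the embryonic cortex, were sorted by GFP and were expanded. Preneoplastic cells were taken 72 h after delivery and tumour cells at 5 to 9 months; the extraction text also names tumours. The 15 preneoplastic libraries were 2 with an empty vector (EV ctl), 3 with Pdgfra overexpression (EV-PDGFRA) and 4 with wild-type histone H3.3, loss of Trp53 and an Atrx hairpin (WT-AP). A further 4 carried a mutant histone H3.3 in place of the wild-type one (K27M-AP), and 2 carried the mutant with added Pdgfra (K27M-APP). The 8 tumour libraries were 3 of K27M-AP T, 4 of K27M-APP T and 1 of K27M-P T, the last without the Atrx hairpin. Total counts per library were 54543839 and 53138075 in EV ctl, 43989080, 51505371 and 48984995 in EV-PDGFRA, and 49821691, 41929255, 50842583 and 52091556 in WT-AP. They were 54100690, 42582772, 51268484 and 45653114 in K27M-AP, 58390900 and 51988699 in K27M-APP, and 46133263, 48347048 and 42213773 in K27M-AP T. They were 41376866, 68642582, 37300947 and 41146985 in K27M-APP T and 45208686 in K27M-P T. The labels do not say that libraries of a group come from separate animals or cultures, so every p-value measures only the spread between these samples.

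The delivered and targeted genes were measured first. Pdgfra (ENSMUSG00000029231, chr5:75152292-75198215, plus strand), the PDGF receptor alpha, stood at 41.4 ± 11.1 CPM in EV ctl (n = 2), 158 ± 78.5 in WT-AP (n = 4) and 218 ± 72.0 in K27M-AP (n = 4). Where it was delivered it stood at 843 ± 441 in EV-PDGFRA (n = 3), 822 ± 49.5 in K27M-APP (n = 2) and 1211 ± 495 in K27M-APP T (n = 4), against 259 ± 170 in K27M-AP T (n = 3). The predicted microRNA gene Mir7025 lies inside Pdgfra and may share its reads. Trp53 (ENSMUSG00000059552, chr11:69580359-69591873, plus strand), which encodes p53, stood at 47.6 ± 5.65 CPM in EV ctl and 42.2 ± 1.81 in EV-PDGFRA. It stood at 18.5 ± 6.14 in WT-AP, 14.7 ± 1.31 in K27M-AP, 18.5 ± 0.102 in K27M-APP, 23.5 ± 22.5 in K27M-AP T and 21.1 ± 4.51 in K27M-APP T. Library 4 of K27M-AP T held 49.5 CPM of Trp53 and 18.3 CPM of Cdkn1a, a cell cycle inhibitor induced by p53. Cdkn1a was at a similar level in K27M-APP T 3 and 4 (16.52 and 20.39 CPM), where Trp53 stood at 19.25 and 15.59. In the other libraries of these 2 tumour groups Cdkn1a stood at 1.247 to 8.678 CPM.

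Atrx (chrX:105797615-105929403, minus strand), a chromatin remodeller that places H3.3, stood at 213 ± 40.3 CPM in EV ctl, 270 ± 34.9 in EV-PDGFRA, 164 ± 67.9 in WT-AP and 129 ± 23.6 in K27M-AP. It stood at 82.8 ± 7.01 in K27M-APP, 75.9 ± 43.2 in K27M-AP T and 76.1 ± 23.2 in K27M-APP T. WT-AP library 1 held 262 CPM of Atrx, above both EV ctl libraries (184 and 241) although its label names the hairpin. Between WT-AP and EV ctl, Atrx was not called (log2 fold change -0.36, adjusted p = 0.707). H3f3a (chr1:180800832-180813943, minus strand) and H3f3b (chr11:116021912-116027962, minus strand), the H3.3 genes, were called in no comparison. In preneoplastic groups H3f3a stood at 273 ± 116 in EV ctl, 224 ± 15.3 in EV-PDGFRA, 254 ± 23.3 in WT-AP, 265 ± 22.2 in K27M-AP and 258 ± 22.8 in K27M-APP. H3f3b stood at 698 ± 90.1, 528.0 ± 10.4, 549 ± 11.6, 626 ± 79.4 and 500.1 ± 5.66 in the same order. In K27M-AP T and K27M-APP T, H3f3a stood at 247 ± 57.1 and 227 ± 34.2 and H3f3b at 792 ± 399.6 and 643 ± 63.7. The counts do not show whether an H3.3 read came from the delivered or the endogenous gene.

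**Figure D1:**
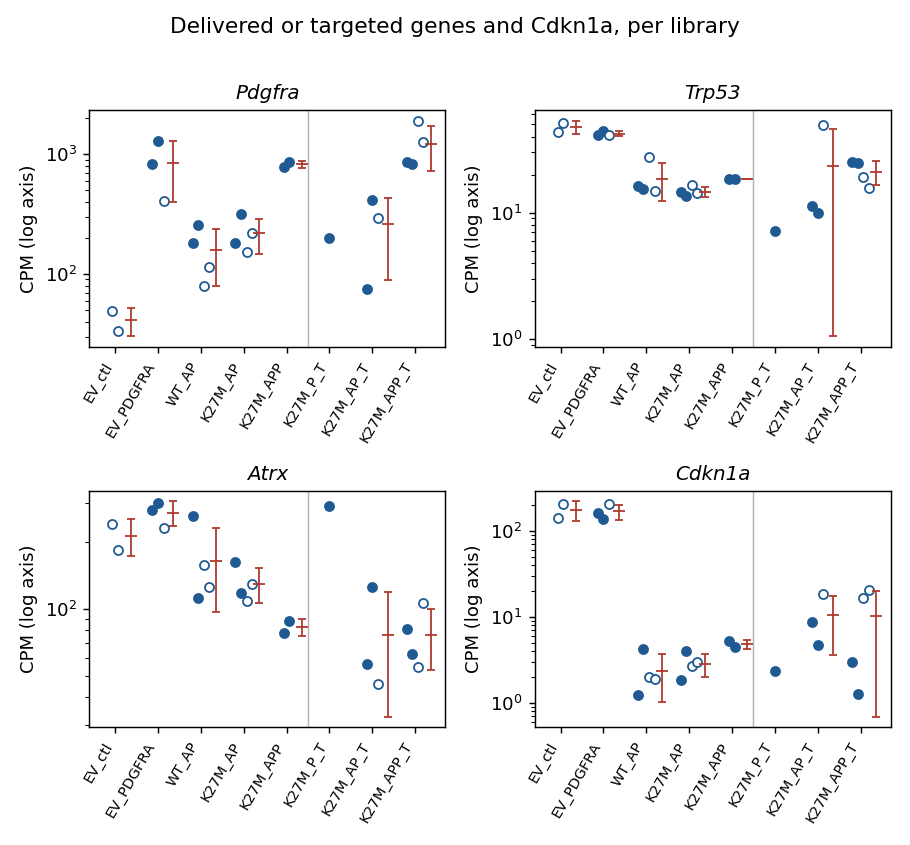
CPM on a log axis for Pdgfra, Trp53, Atrx and Cdkn1a, 1 symbol per library, by group, with preneoplastic groups left of the vertical line. Filled symbols are libraries of the earlier table, open symbols those of the later table alone, and red bars give mean ± SD; values below 0.01 are drawn at 0.01.

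In WT-AP cells (n = 4) p53 target genes fell steeply against EV ctl (n = 2). Trp53 itself fell by 1.35 on the log2 scale (SE 0.22, adjusted p = 0.0194). Cdkn1a (ENSMUSG00000023067) fell from 176 ± 46.0 to 2.33 ± 1.31 CPM, by 75.1-fold (log2 fold change -6.23, adjusted p = 2.82e-05). Eda2r, a death receptor gene of the p53 response, fell from 139 ± 4.604 to 1.83 ± 1.95 CPM (log2 fold change -6.25, adjusted p = 0.00648), and Ccng1, a cyclin G1 gene, from 709 ± 253 to 59.5 ± 8.92 CPM (-3.56, adjusted p = 3.91e-05). Of 28 p53 target genes measured, 14 fell, 0 rose and 14 did not pass; adjusted over the list alone, 22 fell. The median log2 fold change of the list was -1.95, and the list fell at an adjusted p of 3.22e-32 (adjusted p = 2.21e-05 with an estimated correlation). Trp53 was no longer called without EV ctl library 5 (adjusted p = 0.186) or WT-AP libraries 1, 2 or 5 (0.0743, 0.068 and 0.0618), with the table batch as a term (-1.27, 0.0501), or in the later table alone (-1.15, 0.992). Over the alternatives run, the adjusted p of Trp53 was 1.27e-05 to 0.992. Eda2r was lost with only the compared groups in the fit (-6.26, 0.0924) and Ccng1 in the later table (-3.72, 0.498).

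Other large falls in WT-AP were Ano3, an anoctamin (1.28 ± 0.330 against 26.0 ± 3.94 CPM, log2 fold change -4.34, adjusted p = 2.82e-05), and Trp53cor1, a long noncoding RNA induced by p53 (0.916 ± 0.601 against 13.5 ± 7.65 CPM, -3.87, adjusted p = 0.00559). Tnfrsf10b, the TRAIL receptor, stood at 0.953 ± 0.413 against 13.9 ± 12.8 CPM (-3.86, adjusted p = 0.0183) and Ak1, an adenylate kinase, at 8.75 ± 2.45 against 115 ± 3.71 CPM (-3.70, adjusted p = 0.00343). The largest rises were Crispld2, a secreted protein gene (24.5 ± 5.17 against 2.81 ± 0.196 CPM, 3.14, adjusted p = 0.0155), Arhgef3, a guanine nucleotide exchange factor (16.1 ± 4.01 against 2.40 ± 1.27 CPM, 2.76, adjusted p = 0.0497), and B3galt5, a galactosyltransferase (16.2 ± 7.03 against 2.55 ± 0.160 CPM, 2.68, adjusted p = 0.00559). Next were the cell adhesion genes Pcdha2 (39.4 ± 11.1 against 8.34 ± 2.59 CPM, 2.25, adjusted p = 0.00979) and Cntn6 (17.1 ± 5.14 against 3.92 ± 1.63 CPM, 2.14, adjusted p = 0.0342), and the glutamate receptor gene Grik2 (46.0 ± 14.6 against 11.7 ± 5.66 CPM, 1.99, adjusted p = 0.0469). Among cell cycle inhibitors only Cdkn1a was called. Cdkn2a, the Ink4a/Arf gene, stood at 145 ± 24.8 against 39.7 ± 11.6 CPM and passed when adjusted over the list alone. Pdgfra was not called (log2 fold change 1.95, adjusted p = 0.188). Without EV ctl library 5 the 6 named rises and Tnfrsf10b lost their calls (adjusted p: Crispld2 0.196, Arhgef3 0.366, B3galt5 0.118, Pcdha2 0.156, Cntn6 0.299, Grik2 0.371, Tnfrsf10b 0.298). Without WT-AP 1, 2, 3 and 5 Arhgef3 had adjusted p of 0.12, 0.1, 0.0917 and 0.0914 and Grik2 0.12, 0.101, 0.0575 and 0.0749. Without WT-AP 1, 3 and 5 Cntn6 had 0.088, 0.0825 and 0.0897 and Tnfrsf10b 0.0801, 0.0786 and 0.0783. Over all alternatives the highest adjusted p of these 7 genes was 0.833 to 0.992. With only the compared groups in the fit Trp53cor1 had 0.124, and in the later table, with 2 libraries against 2, Ano3 had 0.498 (log2 fold change -4.65), Trp53cor1 0.536 (-4.73) and Ak1 0.992 (-4.08).

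Over all genes 63 were called between WT-AP and EV ctl, 17 higher and 46 lower in WT-AP, 60 of them by at least 2-fold, with 2027 at an unadjusted p under 0.05. The count was 350 without EV ctl library 4, 31 without EV ctl library 5, and 40, 38, 37 and 35 without WT-AP libraries 1, 2, 3 and 5. The later table's libraries alone gave 2, both of them lower, and DESeq2 gave 448.

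Of the other lists, proliferation genes rose in WT-AP as a group, with 25 of 25 positive, a median log2 fold change of 1.01 and an adjusted p of 1.54e-04 (adjusted p = 0.955 with an estimated correlation). No member was called. Top2a, a topoisomerase of dividing cells, stood at 804 ± 66.2 against 334 ± 335 CPM. EV ctl library 5 held 43.1 CPM of Mki67, a marker of dividing cells, and library 4 held 321; without library 5 the list was not called (adjusted p = 0.337). Also lost without library 5 were oligodendrocyte precursor markers (up, adjusted p = 0.0108; 0.791 with an estimated correlation; 0.385 without it; median 0.36 over 18, Ptprz1 1097 ± 139 against 906 ± 346 CPM), mature oligodendrocyte markers (up, 0.0178; 0.791; 0.337; median 1.41 over 14, Cnp 232 ± 144 against 147 ± 106 CPM) and interferon response genes (up, 0.0245; 0.955; 0.676; median 0.41 over 18). Without WT-AP library 1 these 3 lists were also not called (0.0655, 0.0909 and 0.222). The interferon list was also lost with the batch term (0.431), and in the later table the 2 oligodendrocyte lists were (0.203 and 0.152). Over all alternatives with the preset correlation, the adjusted p was 9.32e-06 to 0.337 for proliferation genes, 0.00378 to 0.385 and 0.00263 to 0.337 for the 2 oligodendrocyte lists and 0.0081 to 0.676 for interferon genes.

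Endothelial and pericyte markers rose in WT-AP (adjusted p = 0.011; adjusted p = 0.113 with an estimated correlation; 8 of 10 positive), with Kdr, a VEGF receptor, at 5.49 ± 2.76 against 1.54 ± 0.304 CPM and past the threshold over the list alone. MHC class I and II genes fell (adjusted p = 0.00972; adjusted p = 0.791 with an estimated correlation; 1 of 10 positive), with B2m, the MHC class I light chain, at 79.4 ± 5.85 against 79.5 ± 26.2 CPM. Without EV ctl library 4, neither list was called (0.0671 and 0.322); over all alternatives the adjusted p was 0.00487 to 0.0671 and 0.000232 to 0.322. The 15 other lists had adjusted p of 0.249 to 0.968.

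In EV-PDGFRA cells (n = 3) Pdgfra stood at 843 ± 441 CPM against 41.4 ± 11.1 in EV ctl (n = 2), a log2 fold change of 4.38 (SE 0.614). Its adjusted p was 0.115 with edgeR, over a range of log2 fold change of 3.31 to 4.72 in the alternatives. It was called with DESeq2 (4.36, adjusted p = 9.73e-13), with the batch term (3.64, adjusted p = 0.0211) and without EV-PDGFRA library 3 (4.72, adjusted p = 0.0389). Trp53 stood at 42.2 ± 1.81 against 47.6 ± 5.65 CPM and Cdkn1a at 169 ± 34.6 against 176 ± 46.0 CPM. Among astrocyte markers, Slc4a4, a bicarbonate transporter, stood at 480 ± 62.6 against 126 ± 39.7 CPM, and among oligodendrocyte precursor markers Rlbp1 stood at 4.41 ± 1.22 against 18.0 ± 12.8 CPM, each past the threshold over its list alone. Among imprinted genes the noncoding RNA H19 stood at 2.69 ± 0.653 against 17.4 ± 3.40 CPM, also past it over the list alone. Xist, the X-inactivation RNA of female cells, was lower in EV-PDGFRA but not called (unadjusted p = 0.000144, adjusted p = 0.265 by edgeR). This comparison thus comes with a difference in Xist.

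Proliferation genes rose as a group with Pdgfra (adjusted p = 7.96e-05; adjusted p = 0.735 with an estimated correlation), with 25 of 25 positive and a median log2 fold change of 0.91. None was called, and Top2a stood at 678 ± 297 against 334 ± 335 CPM. Without EV ctl library 5, which held 43.1 CPM of Mki67, the list was not called (adjusted p = 0.319), nor was it in the later table alone (0.118), over a range of 9.73e-07 to 0.319 in all alternatives. The 21 other lists had adjusted p of 0.0587 to 0.882. edgeR called 0 genes in this comparison, with 1420 at an unadjusted p under 0.05. DESeq2 called 101, voom with weights 0 and edgeR with the batch term 2; edgeR called 9 without EV ctl library 4 and 2 without EV-PDGFRA library 3.

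With the mutant histone in place of the wild-type one, 6 genes rose in K27M-AP (n = 4) against WT-AP (n = 4) and 0 fell. Zfp711 (ENSMUSG00000025529, chrX:112600526-112635070, plus strand), an X-linked zinc finger protein, rose 2.46-fold from 11.6 ± 2.50 to 28.6 ± 1.79 CPM (log2 fold change 1.30, SE 0.182, adjusted p = 0.0304). The 5 others were lower in level and were chosen after their values were seen. Plag1 (ENSMUSG00000003282, chr4:3900996-3938423, minus strand), a zinc finger oncogene, stood at 6.32 ± 4.38 against 0.0783 ± 0.0854 CPM (adjusted p = 0.0346), too near zero in WT-AP for a fold. Bcl11a, a transcriptional repressor (chr11:24078056-24174123, plus strand), stood at 9.67 ± 2.48 against 1.79 ± 0.622 CPM (2.43, SE 0.307, adjusted p = 0.0174). AW551984 (chr9:39587396-39604403, minus strand) stood at 1.99 ± 1.11 against 0.185 ± 0.0491 CPM (3.42, SE 0.416, adjusted p = 0.0172). Tcf24 (chr1:9960163-9967932, minus strand) stood at 4.24 ± 1.11 against 0.737 ± 0.255 CPM (2.52, SE 0.351, adjusted p = 0.0304) and Gm10567 at 3.27 ± 0.876 against 0.495 ± 0.135 CPM (2.72, SE 0.31, adjusted p = 0.0168). These last 2 may share reads, so they may count 1 gene.

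In the same comparison Pdgfra stood at 218 ± 72.0 against 158 ± 78.5 CPM, Trp53 at 14.7 ± 1.31 against 18.5 ± 6.14 and Atrx at 129 ± 23.6 against 164 ± 67.9, with adjusted p of 1 for each. Chchd7, the neighbour of Plag1, stood at 10.9 ± 2.85 against 5.02 ± 1.60 CPM and was not called. At an unadjusted p under 0.05 there were 797 genes. The count was 0 without WT-AP library 1 or 3, 1 without WT-AP 5, 4 without K27M-AP 1, 3 without K27M-AP 2 or 3 and 2 without K27M-AP 4 (AW551984 and Gm10567). Within each table, with 2 libraries against 2, it was 0, and it was 3 with the batch term and 64 by DESeq2. It was also 0 with the replicate number as a block and with only the compared groups in the fit, where Zfp711 had adjusted p of 0.264 and 0.226. Zfp711 had a log2 fold change of 1.21 in the earlier table (adjusted p = 1), 1.39 in the later one (0.963) and 1.30 with the batch term (0.0501). It was not called without any one of the K27M-AP libraries (0.113, 0.086, 0.123 and 0.0633 for 1 to 4) or WT-AP 1, 3 or 5 (0.157, 0.174 and 0.138), and its adjusted p over all alternatives was 1.27e-09 to 1.

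**Figure D2:**
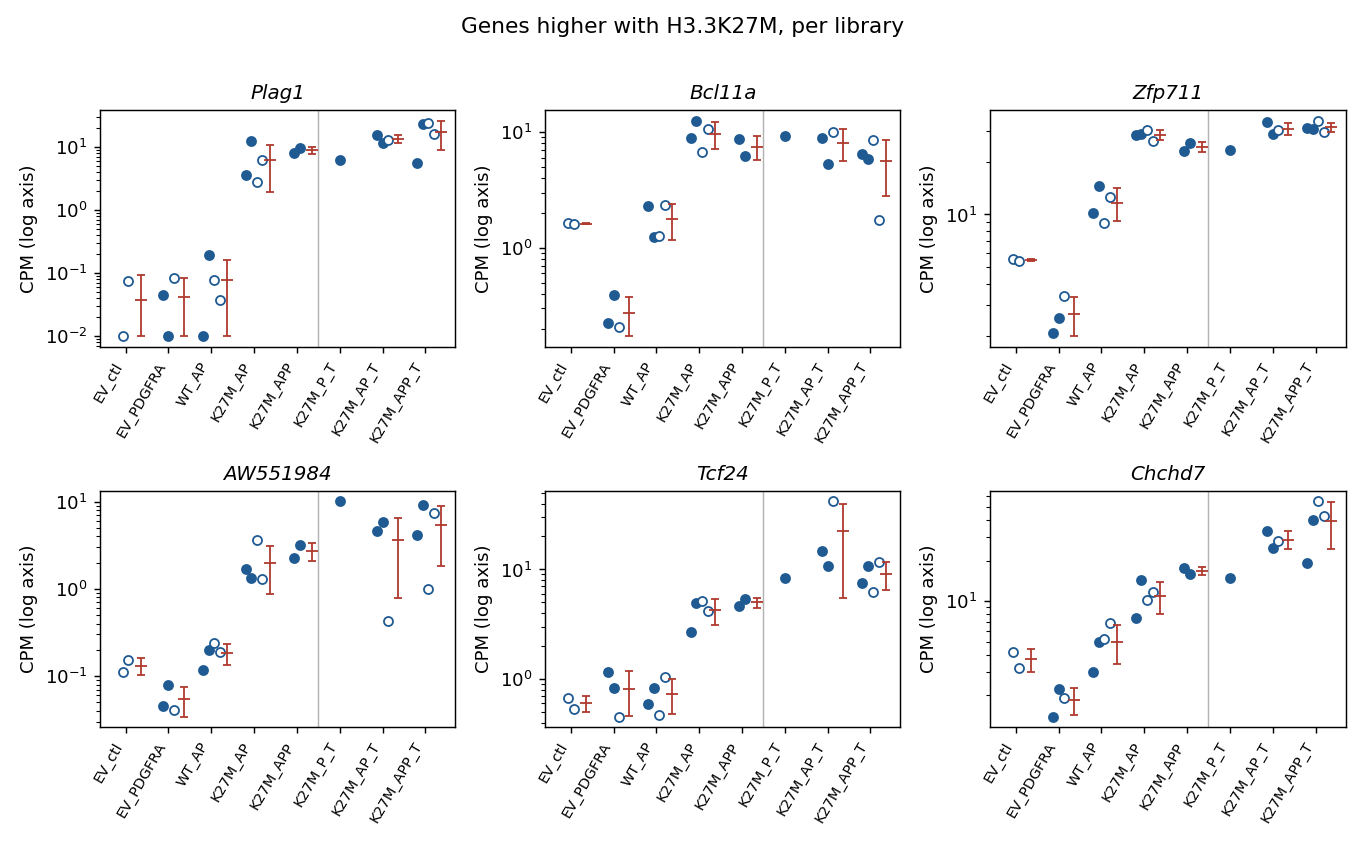
CPM on a log axis for Plag1, Bcl11a, Zfp711, AW551984, Tcf24 and Chchd7, 1 symbol per library, by group, with preneoplastic groups left of the vertical line. Filled symbols are libraries of the earlier table, open symbols those of the later table alone, and red bars give mean ± SD; values below 0.01 are drawn at 0.01.

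As a group, neuron markers rose in K27M-AP, with 21 of 24 positive and a median log2 fold change of 0.91 (adjusted p = 2.01e-04; adjusted p = 0.377 with an estimated correlation). Neurod1, a neurogenic transcription factor, stood at 1.26 ± 1.26 against 0.0705 ± 0.0143 CPM and passed over the list alone, and Map2, a dendrite protein gene, at 1013 ± 111 against 933 ± 143 CPM. Imprinted genes rose (16 of 19 positive, median 0.43, adjusted p = 7.75e-04; adjusted p = 0.0395 with an estimated correlation). Of them, Ndn, a growth suppressor, stood at 59.7 ± 9.04 against 28.2 ± 5.77 CPM and passed over the list alone, and Nnat at 1100 ± 960 against 762 ± 383 CPM. MHC genes rose (9 of 10 positive, median 0.74, adjusted p = 0.00323; adjusted p = 0.377 with an estimated correlation) and interferon response genes rose (16 of 18 positive, median 0.51, adjusted p = 0.00938; adjusted p = 0.579 with an estimated correlation), with no member called. B2m stood at 80.7 ± 17.9 against 79.4 ± 5.85 CPM.

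Proliferation genes fell in K27M-AP (2 of 25 positive, median -0.20, adjusted p = 2.01e-04; adjusted p = 0.579 with an estimated correlation). Top2a stood at 758 ± 496 against 804 ± 66.2 CPM. K27M-AP library 4 held 19.1 CPM of Mki67; without it the list pointed up (adjusted p = 0.135), and within the earlier table it rose (1.19e-05), over a range of 1.59e-07 to 0.135. Receptor tyrosine kinase and MAPK response genes fell (2 of 20 positive, median -0.52, adjusted p = 9.09e-04; adjusted p = 0.396 with an estimated correlation), with Ccnd1, cyclin D1, at 1007 ± 948 against 1470 ± 694 CPM. Hypoxia and glycolysis genes fell (6 of 18 positive, median -0.26, adjusted p = 0.00272; adjusted p = 0.377 with an estimated correlation), with the aldolase gene Aldoa at 337 ± 82.8 against 481 ± 80.6 CPM. A further 14 lists had adjusted p of 0.0766 to 0.977.

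Leaving out a library ended several of these calls. Without K27M-AP library 4 the neuron list (adjusted p = 0.353) and the tyrosine kinase list (0.137) were not called. Without K27M-AP library 2 the neuron (0.112), MHC (0.112) and interferon (0.427) lists were not called. Without WT-AP library 2 the tyrosine kinase (0.153) and interferon (0.109) lists were not called, and the interferon list was also lost without WT-AP 3 (0.0523). Within the earlier table the neuron (0.0726), hypoxia (0.181) and interferon (0.0588) lists were not called, and within the later table the imprinted (0.0883), tyrosine kinase (0.051) and MHC (0.142) lists were not. With the replicate number as a block the tyrosine kinase (0.122), interferon (0.135) and hypoxia (0.175) lists were not called. Over all alternatives with the preset correlation the adjusted p was 2.18e-06 to 0.353 for the neuron list and 0.000886 to 0.0883 for the imprinted list. It was 3.38e-05 to 0.153 for the tyrosine kinase, 0.000725 to 0.181 for the hypoxia, 0.00066 to 0.142 for the MHC and 0.000725 to 0.427 for the interferon list.

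When the mutant histone, Trp53 loss and the Atrx hairpin were present on top of Pdgfra, 392 genes changed in K27M-APP (n = 2) against EV-PDGFRA (n = 3), 183 higher and 209 lower, 345 by at least 2-fold. Trp53 fell from 42.2 ± 1.81 to 18.5 ± 0.102 CPM (log2 fold change -1.19, adjusted p = 0.0315) and Atrx from 270 ± 34.9 to 82.8 ± 7.01 CPM (-1.71, adjusted p = 0.0238). Cdkn1a fell 34.8-fold, from 169 ± 34.6 to 4.84 ± 0.587 CPM (-5.12, adjusted p = 0.000838), and Ccng1 from 969 ± 196 to 62.8 ± 7.50 CPM (-3.95, adjusted p = 0.000301). Of 28 p53 target genes 13 fell, 0 rose and 15 did not pass; adjusted over the list alone, 22 fell. The list fell at an adjusted p of 8.49e-25 (adjusted p = 7.45e-05 with an estimated correlation), with a median log2 fold change of -1.98. Pdgfra, delivered in both groups, stood at 822 ± 49.5 against 843 ± 441 CPM and was not called.

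Among the largest rises, Grb10, an imprinted inhibitor of insulin receptor signalling, rose from 2.63 ± 3.39 to 278 ± 9.96 CPM (log2 fold change 6.72, adjusted p = 0.0215), and Grin2c, a glutamate receptor subunit, from 0.657 ± 0.462 to 63.4 ± 17.7 CPM (6.58, adjusted p = 0.0054). Igf2bp1, an RNA-binding protein of growing tissue, stood at 33.1 ± 5.17 against 0.0288 ± 0.025 CPM (adjusted p = 0.00905), the imprinted gene Zdbf2 at 31.6 ± 9.25 against 0.0407 ± 0.0414 (adjusted p = 0.00612), and the amino acid transporter gene Slc38a4 at 53.6 ± 1.74 against 0.144 ± 0.25 (adjusted p = 0.0215). These last 3 lay near zero in EV-PDGFRA, so no fold is given. Imprinted genes rose as a list, 4 of 19 called (adjusted p = 0.00397; adjusted p = 0.0411 with an estimated correlation), namely Grb10, Ndn (81.1 ± 22.1 against 30.7 ± 7.23 CPM, adjusted p = 0.015) and, chosen after their values were seen, Asb4 (18.2 ± 3.28 against 0.728 ± 0.777 CPM, 4.64, adjusted p = 0.0235) and Sgce (39.4 ± 3.09 against 23.8 ± 2.52 CPM, 0.73, adjusted p = 0.0473). Without EV-PDGFRA 1 the adjusted p was 0.0982 for Grb10, 0.0632 for Igf2bp1, 0.092 for Slc38a4 and 0.0519 for Ndn, without EV-PDGFRA 2 it was 0.0508 for Ndn, and without EV-PDGFRA 3 it was 0.0676 for Grb10 and 0.0786 for Slc38a4. Without K27M-APP 1 it was 0.107 for Grb10, 0.0502 for Igf2bp1, 0.107 for Slc38a4 and 0.255 for Ndn, and without K27M-APP 2 it was 0.0948, 0.0601 and 0.0997 for the first 3. The highest over all alternatives was 0.107 for Grb10 and Slc38a4, 0.112 for Igf2bp1 and 0.723 for Ndn.

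The largest falls were Svop (0.256 ± 0.0282 against 19.1 ± 3.55 CPM, -6.21, adjusted p = 0.044), a synaptic vesicle gene, and Eda2r (3.80 ± 1.16 against 140 ± 10.2 CPM, -5.19, adjusted p = 0.0339). Ak1 stood at 6.90 ± 1.13 against 201 ± 29.7 CPM (-4.86, adjusted p = 0.00282), Klhdc7a at 0.603 ± 0.0407 against 16.8 ± 2.81 CPM (-4.79, adjusted p = 0.00864), and Fas, a death receptor gene, at 0.448 ± 0.131 against 12.3 ± 2.59 CPM (-4.76, adjusted p = 0.00343). Prom1, a stem cell marker, rose from 3.10 ± 2.42 to 42.4 ± 6.12 CPM (3.77, adjusted p = 0.0241), and Slc4a4, an astrocyte marker, fell from 480 ± 62.6 to 116 ± 37.1 (-2.05, adjusted p = 0.0394). Cdkn2a rose from 38.1 ± 13.0 to 106 ± 2.74 (1.48, adjusted p = 0.0486). Among polycomb-regulated developmental regulators the RNA-binding gene Igf2bp2 rose from 13.4 ± 2.21 to 71.1 ± 0.111 (2.41, adjusted p = 0.0312) and the homeobox gene Irx3 fell, standing at 0.0169 ± 0.0239 against 2.73 ± 1.24 (adjusted p = 0.00594). Cbx6, a polycomb complex member, fell from 131 ± 6.19 to 67.2 ± 8.91 (-0.97, adjusted p = 0.0435). Xist, the X-inactivation RNA of female cells, stood at 105 ± 53.3 against 0.0719 ± 0.0547 CPM (adjusted p = 0.0244), while Ddx3y, on the Y chromosome, stood at 83.3, 66.3 and 87.2 CPM in the EV-PDGFRA libraries and at 40.3 and 24.96 in K27M-APP. Leaving out any 1 of the 5 libraries ended the calls of Svop (adjusted p at most 0.379), Eda2r (0.342), Slc4a4 (0.388), Cdkn2a (0.301), Igf2bp2 (0.203), Cbx6 (0.392 without K27M-APP 1) and Xist (0.129 without K27M-APP 2). Without K27M-APP 1 and 2 the adjusted p was 0.0556 and 0.0674 for Ak1, 0.172 and 0.158 for Klhdc7a, 0.0556 and 0.0798 for Fas, 0.0556 and 0.101 for Irx3, and 0.175 and 0.119 for Prom1. Prom1 was also lost without EV-PDGFRA 1 (0.112) or 3 (0.0814).

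Interferon response genes rose as a list, with 16 of 18 positive and none called (adjusted p = 0.00114; adjusted p = 0.64 with an estimated correlation). Within the earlier table the list was not called (0.111; range over all alternatives 2.67e-05 to 0.111). The 19 other lists had adjusted p of 0.108 to 0.884. At an unadjusted p under 0.05 there were 3133 genes. The count of 392 was 653 within the earlier table, 281 of them shared, and 413 with the batch term. It was 44 and 45 without K27M-APP 1 and 2, and 92, 162 and 131 without EV-PDGFRA 1, 2 and 3. DESeq2 gave 1371 and voom with weights 5142. Cdkn1a, Ccng1, Grin2c and Zdbf2 were called in every alternative, while Trp53 was lost without any 1 of the 5 libraries (adjusted p 0.0791 to 0.286), and Atrx without EV-PDGFRA 1 (0.0774) or 2 (0.0612) or K27M-APP 1 (0.265) or 2 (0.212).

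With Pdgfra added to K27M-AP, Pdgfra stood at 822 ± 49.5 CPM in K27M-APP (n = 2) against 218 ± 72.0 in K27M-AP (n = 4), a log2 fold change of 1.94 (adjusted p = 0.667). Oligodendrocyte precursor markers fell as a list (1 of 18 positive, median -1.08, adjusted p = 3.4e-05; adjusted p = 0.633 with an estimated correlation), with Ptprz1, a receptor phosphatase, at 633 ± 141 against 965 ± 227 CPM. Mature oligodendrocyte markers fell (2 of 14 positive, adjusted p = 0.0371; 0.633 with an estimated correlation), with Cnp, a myelin enzyme, at 75.8 ± 11.97 against 293 ± 250 CPM, and neuron markers fell (4 of 24 positive, adjusted p = 0.00641; 0.633 with an estimated correlation), with Map2 at 821 ± 50.6 against 1013 ± 111. Proliferation genes rose (25 of 25 positive, median 0.61, adjusted p = 6.62e-06; 0.633 with an estimated correlation), with Top2a at 1164 ± 46.0 against 758 ± 496 CPM. Tyrosine kinase and MAPK response genes rose (17 of 20 positive, adjusted p = 6.4e-04; 0.633 with an estimated correlation), with Ccnd1 at 2135 ± 145 against 1007 ± 948, and hypoxia genes rose (14 of 18 positive, adjusted p = 0.0465; 0.633 with an estimated correlation), with Aldoa at 408 ± 13.9 against 337 ± 82.8. No member of these 6 lists was called.

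K27M-AP library 4, which held 19.1 CPM of Mki67, weighed on these lists: without it the neuron and mature oligodendrocyte lists were not called (0.122 and 0.275). The mature oligodendrocyte list was also lost without K27M-APP 2 (0.0777), and the hypoxia list without K27M-AP 1 or 3 (0.0595 and 0.118) or K27M-APP 1 (0.215). Within the earlier table the neuron (0.0886), mature oligodendrocyte (0.161) and hypoxia (0.0853) lists were not called, with the batch term they had 0.0632, 0.145 and 0.0632, and with the replicate block 0.138, 0.336 and 0.0712. Over all alternatives these 3 lists had adjusted p of 0.000623 to 0.138, 0.0207 to 0.336 and 0.0191 to 0.215. The 16 other lists had adjusted p of 0.0681 to 0.993. Of polycomb-regulated genes, the homeobox genes Irx1, Irx2 and Irx3 were lower in K27M-APP and passed over the list alone (adjusted p = 0.0398 for each). Irx3 lay near zero in K27M-APP, and no folds are given. edgeR called 0 genes, with 1200 at an unadjusted p under 0.05, DESeq2 6 and voom with weights 2.

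The Pdgfra effect was then set against its effect in EV cells, where the 2 groups also differed in Xist. Oligodendrocyte precursor markers (2 of 18 positive, median -0.91, adjusted p = 0.00573; adjusted p = 0.628 with an estimated correlation) and astrocyte markers (2 of 15 positive, median -1.13, adjusted p = 0.0165; adjusted p = 0.628 with an estimated correlation) had a lower effect in the K27M-AP background. Tyrosine kinase and MAPK response genes had a higher one (16 of 20 positive, median 0.33, adjusted p = 0.0245; adjusted p = 0.673 with an estimated correlation). The differences of log2 fold change were -0.90 for Ptprz1, -3.01 for the astrocyte gene Apoe and -0.28 for Ccnd1, the last against the direction of its list. Without EV ctl 5 (0.233, 0.729 and 0.914) or K27M-AP 4 (0.0755, 0.242 and 0.467) none of the 3 was called. Without K27M-APP 1 the precursor and kinase lists were not called (0.0593 and 0.159), nor was the kinase list without K27M-AP 2 (0.0609). Over all alternatives the 3 lists had adjusted p of 0.00108 to 0.233, 0.00132 to 0.729 and 0.00174 to 0.914. The 19 other lists had adjusted p of 0.0913 to 0.929. edgeR called 0 genes (494 at an unadjusted p under 0.05; DESeq2 6, voom with weights 0), and 4 without EV ctl 4.

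In tumours of K27M-AP (n = 3) against the preneoplastic cells (n = 4), 5 genes rose and 0 fell. Samd9l, an interferon-induced gene, rose from 4.30 ± 1.74 to 47.6 ± 22.3 CPM (log2 fold change 3.45, SE 0.394, adjusted p = 0.0262) and Ifi27, also interferon-induced, from 22.5 ± 8.37 to 284 ± 177 (3.64, SE 0.469, adjusted p = 0.0443). Nol3, an inhibitor of apoptosis, rose from 5.63 ± 0.895 to 24.7 ± 5.75 (2.11, SE 0.292, adjusted p = 0.0443). Lgals9, a galectin, rose from 0.603 ± 0.247 to 57.9 ± 77.0 (6.56, SE 0.92, adjusted p = 0.0443), standing at 5.57, 21.8 and 146 in the 3 tumours. Lgi1, chosen after its values were seen, rose from 0.123 ± 0.0282 to 1.34 ± 0.627 (3.39, SE 0.46, adjusted p = 0.0443). Pdgfra stood at 259 ± 170 against 218 ± 72.0, Trp53 at 23.5 ± 22.5 against 14.7 ± 1.31 and Atrx at 75.9 ± 43.2 against 129 ± 23.6, none of them called. Without K27M-AP 1, 3 and 4 and K27M-AP T 4 the adjusted p was 0.17, 0.151, 0.0969 and 0.069 for Samd9l, 0.17, 0.152, 0.105 and 0.0759 for Ifi27, 0.198, 0.168, 0.105 and 0.147 for Nol3 and 0.208, 0.168, 0.131 and 0.069 for Lgals9. Without K27M-AP 2 it was 0.107 for Ifi27, Nol3 and Lgals9. Within the earlier table (2 tumours against 2 libraries) it was 0.219 for each of these 4 genes, with log2 fold changes of 3.25 for Samd9l, 4.13 for Ifi27, 2.01 for Nol3 and 4.68 for Lgals9. Within the later one (a single tumour against 2 libraries) it was 0.569, 0.48, 0.728 and 0.48, the highest of all alternatives, with 3.73, 3.25, 2.36 and 7.75.

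Interferon response genes rose together in K27M-AP tumours: 19 of 19 were positive, 0 were called over all genes and 18 passed over the list alone, with a median log2 fold change of 3.05 (adjusted p = 1.28e-16; adjusted p = 0.149 with an estimated correlation). Isg15, a ubiquitin-like protein, stood at 27.4 ± 21.5 against 1.66 ± 0.352 CPM, and Ifi44 at 32.4 ± 26.8 against 1.82 ± 0.533. The tumours differed: the list summed to 253, 1070 and 1220 CPM in K27M-AP T 1, 2 and 4, against 103, 194, 126 and 159 in K27M-AP, and in K27M-AP T 1 Irf9 (12 CPM) and Mx1 (0.389) lay within the range of the K27M-AP libraries. MHC genes rose too (9 of 10 positive, 6 past the threshold over the list alone, median 1.73, adjusted p = 1.48e-06; adjusted p = 0.149 with an estimated correlation). B2m stood at 273 ± 157 against 80.7 ± 17.9, H2-D1 at 168 ± 89.6 against 24.3 ± 10.9 and the peptide transporter gene Tap1 at 35.5 ± 21.1 against 7.42 ± 4.74. Both lists were called in every alternative but the estimated correlation.

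Astrocyte markers fell in these tumours (1 of 15 positive, median -1.50, adjusted p = 2.03e-04; adjusted p = 0.268 with an estimated correlation). Aqp4, a water channel, stood at 2.92 ± 1.21 against 64.1 ± 92.3 CPM and Aldoc at 127 ± 26.1 against 357 ± 223, both past the threshold over the list alone; Apoe stood at 102 ± 101 against 919 ± 1350, with 2888 in K27M-AP library 4. Fibroblast and matrix genes rose (10 of 13 positive, adjusted p = 0.00166; adjusted p = 0.149 with an estimated correlation), with the collagen genes Col3a1 at 8.70 ± 9.55 against 0.524 ± 0.291 and Col5a1 at 122 ± 30.1 against 42.4 ± 18.1. Of 39 Hox genes only 6 passed the filter on low counts, through the tumour libraries, so that their direction was set by the filter; the list test (up, adjusted p = 2.03e-04; adjusted p = 0.268 with an estimated correlation) says nothing of the other members. The highest level was 6.71 CPM, for Hoxa4 in K27M-AP T 1. In the later table, where a single tumour of this group lies, the Hox list pointed down (0.71; range over all alternatives 9.42e-12 to 0.71).

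Further lists had weaker calls in K27M-AP tumours. Proliferation genes rose (21 of 25 positive, adjusted p = 0.00198; adjusted p = 0.567 with an estimated correlation), with Top2a at 1304 ± 306 against 758 ± 496 CPM; without K27M-AP library 4 (0.483) and in the earlier table (0.671) the list pointed down, over a range of 7.83e-06 to 0.671. Oligodendrocyte precursor markers fell (3 of 18 positive, adjusted p = 0.00576; adjusted p = 0.421 with an estimated correlation), with Ptprz1 at 636 ± 379 against 965 ± 227, and neural stem cell markers fell (8 of 19 positive, adjusted p = 0.0474; 0.212). Vim, the neural stem cell marker with the highest mean, went against its list, at 4863 ± 4473 against 1747 ± 682. Endothelial markers rose (9 of 14 positive, adjusted p = 0.0426; 0.268), with Kdr at 13.0 ± 3.00 against 4.19 ± 0.231 past the threshold over the list alone. More endothelial markers were tested here than in the preneoplastic fit. The added ones may have passed the filter through tumour libraries, which would set their direction. Polycomb-regulated genes rose (13 of 19 positive, adjusted p = 0.0284; 0.149), with Igf2bp2 at 56.8 ± 22.6 against 47.8 ± 15.6, and kinase and MAPK response genes rose (16 of 20 positive, adjusted p = 0.0485; 0.542), with Ccnd1 at 1748 ± 580 against 1007 ± 948. Sex-linked genes fell (0 of 5 positive, adjusted p = 0.0272; 0.268), with Xist at 56.2 ± 97.4 against 119 ± 47.3, and the lymphocyte list held a single measured gene, Lck (0.759 ± 0.276 against 0.292 ± 0.124; up, adjusted p = 0.0284; 0.149). The second p in each bracket is the adjusted p with an estimated correlation.

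Libraries ended those calls as follows. The precursor list was lost without K27M-AP 4 (adjusted p = 0.067) or K27M-AP T 1 (0.0854) or 4 (0.0871), and the polycomb-regulated list without K27M-AP 1 (0.102) or 3 (0.0826) or K27M-AP T 1 (0.0854). Endothelial markers were not called without K27M-AP 1, 2 or 3 (0.102, 0.0501 and 0.185) or K27M-AP T 1 or 2 (0.18 and 0.29). Neural stem cell markers were not called without K27M-AP 1 or 2 (0.0808 and 0.136) or K27M-AP T 1 or 2 (0.139 and 0.0667). The kinase list was lost without K27M-AP 2 or 4 (0.119 and 0.316) or K27M-AP T 1, 2 or 4 (0.112, 0.097 and 0.0839), the sex-linked list without K27M-AP 3 (0.0516) or K27M-AP T 1 (0.133), and Lck without K27M-AP T 2 (0.0667). Within the earlier table the precursor and kinase lists were not called (0.189 and 0.0997), and within the later table the endothelial (0.66), neural stem (0.66), kinase (0.243) and Lck (0.147) lists were not. With the replicate block the endothelial list and Lck (0.0591 and 0.0727), and with the batch term the endothelial and kinase lists (0.0542 and 0.0758), were not called. Over all alternatives the adjusted p was 2.73e-05 to 0.189 for the precursor, 0.00695 to 0.102 for the polycomb-regulated, 0.00579 to 0.66 for the endothelial, 0.00421 to 0.66 for the neural stem, 0.0082 to 0.316 for the kinase, 1.21e-06 to 0.133 for the sex-linked list and 0.0173 to 0.147 for Lck.

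Over all genes 2486 had an unadjusted p under 0.05. The count of 5 was 0 within the earlier table (2 libraries against 2), 0 with only the compared groups in the fit, 29 with the replicate block and 20 with the batch term. It was 0 without K27M-AP 1, 3 or 4 or K27M-AP T 4, 1 without K27M-AP 2, and 33 and 54 without K27M-AP T 1 and 2. DESeq2 gave 578 and voom with weights 115. With only the compared groups the adjusted p was 0.145 for Samd9l, Ifi27 and Nol3 and 0.19 for Lgals9. With the block it was 0.0515 for Lgals9. The 9 other lists had adjusted p of 0.149 to 0.998.

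Tumours of K27M-APP (n = 4) against their preneoplastic cells (n = 2) had the same list at the head. Interferon response genes rose (19 of 19 positive, 14 past the threshold over the list alone, median log2 fold change 2.53, adjusted p = 3.75e-20; adjusted p = 0.24 with an estimated correlation). Isg15 stood at 23.1 ± 14.9 against 2.87 ± 1.10 CPM and Ifi44 at 20.2 ± 12.2 against 3.06 ± 0.641. Outside the list, Ifi27 stood at 324 ± 121 against 25.8 ± 2.16 and Samd9l at 52.6 ± 15.4 against 7.52 ± 0.00439. MHC genes rose (10 of 10 positive, 4 past the threshold over the list alone, median 1.11, adjusted p = 1.06e-07; adjusted p = 0.24 with an estimated correlation), with B2m at 216 ± 71.4 against 91.98 ± 1.04 and H2-D1 at 158 ± 101 against 26.0 ± 5.05. Both were called in every alternative but the estimated correlation. Pdgfra stood at 1211 ± 495 against 822 ± 49.5, Trp53 at 21.1 ± 4.51 against 18.5 ± 0.102 and Atrx at 76.1 ± 23.2 against 82.8 ± 7.01, none called.

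**Figure D3:**
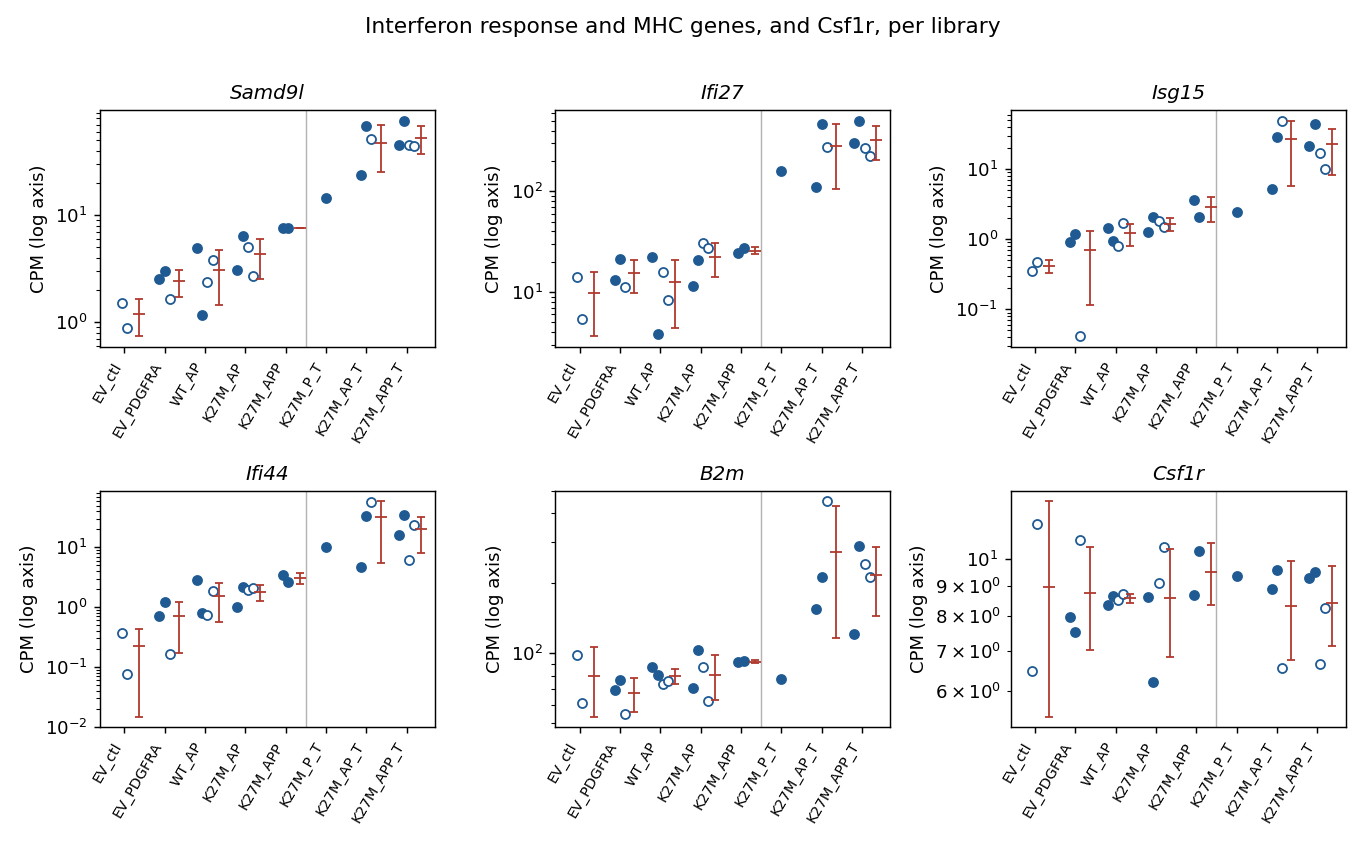
CPM on a log axis for Samd9l, Ifi27, Isg15, Ifi44, B2m and the macrophage marker Csf1r, 1 symbol per library, by group, with preneoplastic groups left of the vertical line. Filled symbols are libraries of the earlier table, open symbols those of the later table alone, and red bars give mean ± SD; values below 0.01 are drawn at 0.01.

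Fibroblast and matrix genes rose in K27M-APP tumours (12 of 13 positive, adjusted p = 0.00749; adjusted p = 0.24 with an estimated correlation), with Col5a1 at 84.9 ± 19.2 against 64.3 ± 14.8 CPM. Endothelial markers rose (12 of 14 positive, adjusted p = 0.00749; adjusted p = 0.24 with an estimated correlation), with Kdr at 10.2 ± 4.92 against 5.96 ± 1.70. As in K27M-AP tumours, some of these markers may have passed the filter only through tumour libraries. The same 6 of 39 Hox genes were tested, with the same limit (up, adjusted p = 0.00434; adjusted p = 0.609 with an estimated correlation). Kinase and MAPK response genes fell (4 of 20 positive, adjusted p = 0.0158; adjusted p = 0.752 with an estimated correlation), with Ccnd1 at 1471 ± 587 against 2135 ± 145, and sex-linked genes fell (2 of 5 positive, adjusted p = 0.00722; adjusted p = 0.24 with an estimated correlation), with Xist at 74.5 ± 149 against 105 ± 53.3. Without K27M-APP 1 the endothelial and kinase lists were not called (0.218 and 0.345), nor was the endothelial list without K27M-APP T 3 (0.103), the sex-linked list without K27M-APP T 3 (0.0834), the kinase list without K27M-APP T 1 or 2 (0.0713 and 0.308) or the Hox list without K27M-APP T 4 (0.0642). Within the earlier table the endothelial (0.363) and sex-linked (0.769) lists were not called, nor was the sex-linked list with the replicate block (0.117). Over all alternatives the adjusted p was 0.000738 to 0.363 for the endothelial, 6.51e-06 to 0.345 for the kinase, 0.000505 to 0.769 for the sex-linked and 0.000859 to 0.0642 for the Hox list. The 15 other lists had adjusted p of 0.433 to 0.883. edgeR called 0 genes, with 678 at an unadjusted p under 0.05, DESeq2 62 and voom with weights 33.

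Between the 2 kinds of tumour, Pdgfra stood at 1211 ± 495 CPM in K27M-APP T (n = 4) against 259 ± 170 in K27M-AP T (n = 3), a log2 fold change of 2.24 with an adjusted p of 1 by edgeR and 0.0131 by DESeq2. Astrocyte markers were higher in K27M-APP T as a list (14 of 15 positive, median 0.70, adjusted p = 0.00276; adjusted p = 0.709 with an estimated correlation), with Apoe at 122 ± 100 against 102 ± 101. The list was not called without K27M-AP T 1 (0.169) or K27M-APP T 2 (0.117) or within the later table (0.203), over a range of 2.06e-05 to 0.203. The 21 other lists had adjusted p of 0.0643 to 0.959. edgeR called 0 genes, with 543 at an unadjusted p under 0.05, DESeq2 11 and voom with weights 2; edgeR called 1 without K27M-APP T 3 and 1 within the earlier table.

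The step from cells to tumour was also compared between the 2 backgrounds. In K27M-APP it was higher for astrocyte markers (15 of 15 positive, median 1.93, adjusted p = 0.000469; adjusted p = 0.515 with an estimated correlation) and oligodendrocyte precursor markers (17 of 18 positive, median 1.12, adjusted p = 0.0119; adjusted p = 0.672 with an estimated correlation). It was lower for proliferation genes (1 of 25 positive, median -0.49, adjusted p = 0.000919; adjusted p = 0.783 with an estimated correlation) and kinase and MAPK response genes (2 of 20 positive, median -0.74, adjusted p = 0.000938; adjusted p = 0.515 with an estimated correlation). The differences of log2 fold change were 4.53 for Apoe, 0.96 for Ptprz1, -0.70 for Top2a and -1.33 for Ccnd1. Without K27M-AP 4 the precursor and proliferation lists were not called (0.0964 and 0.337). Nor was the precursor list without K27M-AP T 1 or 4 (0.0681 and 0.239), K27M-APP 1 (0.0739) or K27M-APP T 4 (0.0673), and within the earlier table neither was (0.0743 and 0.697), nor was the proliferation list with the batch term (0.107), over ranges of 7.09e-05 to 0.239 and 1.2e-05 to 0.697. The 18 other lists had adjusted p of 0.101 to 0.994. edgeR called 0 genes (723 at an unadjusted p under 0.05; DESeq2 2, voom with weights 0).

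4 lists were called in no comparison or interaction. Over these 10 tests the adjusted p was 0.277 to 0.993 for microglia and macrophage markers, 0.133 to 0.764 for red blood cell markers, 0.472 to 0.977 for cell cycle inhibitors and 0.121 to 0.96 for the polycomb complexes. Csf1r, a macrophage receptor, reached at most 9.64 CPM in a tumour and C1qb, a complement gene of microglia, 0.0536.

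Across all 23 libraries the first 2 principal components of the 1000 most variable genes held 26.1% and 21.6% of the variance. The second separated the 13 libraries of the earlier table from the 10 of the later table alone. Both EV ctl libraries lay in the later table and both K27M-APP libraries in the earlier one, so comparisons of these groups cross the tables. K27M-AP library 4 stood apart in its cell type markers as well as in Mki67, with 373 CPM of the astrocyte gene Gfap, 337 of the myelin gene Mbp and 67.3 of the neuronal gene Dcx. Mitochondrial genes held 0.676% of counts in K27M-P T, 0.708% in K27M-AP T 2 and 0.749% in K27M-APP T 2, and 1.44 to 3.86% in the others. The most counted gene, the 7SL RNA Metazoa_SRP, held 3.36 to 7.37%.

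**Figure D4:**
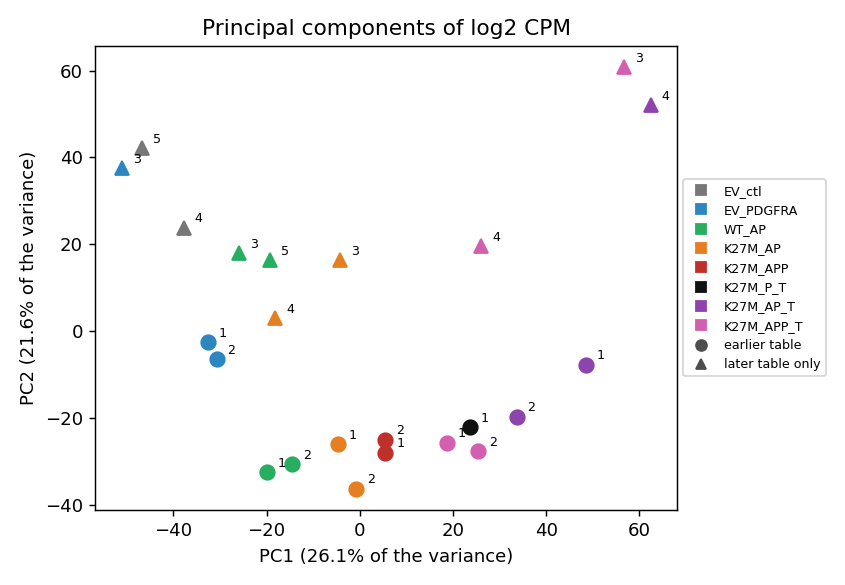
Principal component 1 against principal component 2 of the 1000 most variable genes, in log2 CPM, 1 symbol per library, coloured by group and numbered by replicate. Circles are libraries of the earlier table and triangles those of the later table alone.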

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

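The tests of explanations and the counts over other splits of the libraries below were chosen only after the results were seen.

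In both tumour comparisons interferon response genes were higher as a list at the preset correlation, though not with an estimated one (adjusted p = 0.149 and 0.24), and 0 members of the list were called over all genes by edgeR. Immune cells in the tumours are argued against: immune markers summed to 40.6 ± 5.49 CPM in 7 tumours and 43.5 ± 14.3 in 6 preneoplastic libraries (ratio 0.934), while the interferon list summed to 764 ± 408 and 152 ± 33.7. The highest CPM in a tumour was 9.64 for Csf1r, 1.94 for P2ry12 and 0.0536 for C1qb, and the labels describe a GFP sort, which would remove such cells, although they also name extraction from tumours. The table batch and a single library are argued against too, with a lowest median log2 fold change of 2.27 within the earlier table and 2.07 over 13 fits that each left out 1 library (highest adjusted p 3.81e-10 at the preset correlation). An interferon response of the tumour cells may be a candidate explanation and remains a hypothesis. The age of the animals also differs, and any difference in culture is not stated. Sex-linked genes, Xist among them, were also lower as a list in both comparisons at the preset correlation, though not with an estimated one. The part of male and female cells in the interferon difference was not tested.

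Library 4 of K27M-AP stood apart from the others of its group, with Mki67 at 19.1 CPM against 684 ± 127, 2.79% of their level. A mislabelled empty vector library is argued against, since on 14 p53 target genes its median position was 8.29, with 0 for its group and 100 for EV ctl (quartiles -4.04 and 25). Dilution by cells without the delivered genes is argued against only as the whole source of the Mki67 loss. The 50 genes higher in its group kept a median of 51.9% of their level above WT-AP (quartiles 14.4 and 107), against 2.79% for Mki67. These 50 genes do not exclude a partial dilution. A mislabelled wild-type H3.3 library cannot be told apart: on those 50 genes its median position was 73, with 0 for WT-AP and 100 for its group (quartiles 25.1 and 109). With WT-AP 1, 2, 3 and 5 held out of the choice of genes in turn, it lay above the 3 others on 35, 41, 37 and 39 of 50 genes against 11, 38, 13 and 21 for the held-out library. Over all genes tested, K27M-AP library 4 lay above those 3 on 35.6, 32.9, 31.3 and 31.4%. It was nearer its group on at least 62.5% of 4 to 8 genes with a 4-fold gap (held-out libraries at most 50%), and on at least 60.5% of 59 to 86 genes also called higher in K27M-APP against EV-PDGFRA (held-out libraries 10, 50, 5.08 and 18%), so held-out WT-AP 2 came close to it; Plag1 at 6.35 CPM and Bcl11a at 10.6 lay among its own group and above WT-AP (highest 0.197 and 2.35), and no biological explanation was tested.

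The 392 genes called between K27M-APP and EV-PDGFRA came with a difference in Xist, low in the 3 EV-PDGFRA libraries. Male and female cells in different shares are argued against as the main source: over 362 autosomal called genes, the median ratio of the change from EV-PDGFRA to EV ctl, which also holds Xist, to that in K27M-APP was 0.149 (quartiles 0.00126 and 0.351), though both changes share the EV-PDGFRA libraries. X-linked genes were 7.42% of the called and 4.47% of the tested genes. The table batch is argued against, since 281 of the genes, 71.7%, were called again in the same direction within the earlier table. The delivered genes and Trp53 loss, which the design names, may account for some of these genes, a hypothesis that was not tested.

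Other splits of the same libraries were counted. For K27M-AP against WT-AP, 3 of 35 splits gave at least the real 6 genes, so this count alone does not exclude chance. All 6 genes were also called higher in K27M-APP against EV-PDGFRA, which shares no library. The 2 comparisons share 1 fit and its estimate of each gene's spread. That can favour calls of the same genes, but it does not set their direction. The log2 fold changes there ran from 2.52 for Gm10567 (SE 0.374) to 4.75 for Bcl11a (SE 0.418), leaving out Plag1 and AW551984, near zero in EV-PDGFRA. The shared direction argues against chance for these 6 genes as a set, though it names no cause. Tcf24 and Gm10567 may count 1 gene. The highest other split gave 3299, from K27M-AP 1 and 3 with WT-AP 3 and 5 on 1 side, and the split that follows the tables gave 216. Those counts point to a structure of the samples. Within each table, with 2 libraries against 2, edgeR gave 0 and the log2 fold change of Zfp711 was 1.21 and 1.39 (1.30 over all), so the lost calls there do not tell where the 6 genes come from. For K27M-AP T against K27M-AP, 3 of 35 splits gave at least the real 5, with 19 the highest other and 1 for the split that follows the tables, so this count alone does not exclude chance. The 5 genes were also higher in K27M-APP T against K27M-APP, which shares no library, each at an unadjusted p of at most 0.0101 (Nol3), though none was called there. The 2 tumour comparisons share 1 fit and its estimate of each gene's spread, so they are not independent. For K27M-APP T against K27M-AP T the real count was 0, which all 35 splits reach of necessity, so this count says nothing about chance; the highest other was 131.

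Single libraries lay far from the others of their group in 4 of 102 tests, where chance gives about 5%. Trp53 stood at 27.7 CPM in WT-AP 3 (others 14.8 to 16.3), and Eda2r at 4.72 in WT-AP 2 (0.56 to 1.23). The polycomb complex list had a mean log2 CPM of 5.31 in WT-AP 2 (5.16 to 5.18), and the total count of K27M-APP T 2 was 68642582 (37300947 to 41376866).

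A test of the difference between backgrounds passed for 7 lists at the preset correlation, and for none of these 7 with an estimated one. For the effect of Pdgfra in K27M-AP against EV cells the adjusted p was 0.00573 for oligodendrocyte precursor, 0.0165 for astrocyte and 0.0245 for tyrosine kinase and MAPK response genes, and 0.628, 0.628 and 0.673 with an estimated correlation. All 3 were lost without EV ctl 5 (0.233, 0.729 and 0.914) or K27M-AP 4 (0.0755, 0.242 and 0.467), the precursor and kinase lists without K27M-APP 1 (0.0593 and 0.159) and the kinase list without K27M-AP 2 (0.0609). For the step to tumour in K27M-APP against K27M-AP the adjusted p was 0.0119 for oligodendrocyte precursor, 0.000469 for astrocyte, 0.000919 for proliferation and 0.000938 for tyrosine kinase and MAPK response genes, and 0.672, 0.515, 0.783 and 0.515 with an estimated correlation. The precursor and proliferation lists were lost without K27M-AP 4 (0.0964 and 0.337), and the precursor list without K27M-AP T 1 or 4 (0.0681 and 0.239), K27M-APP 1 (0.0739) or K27M-APP T 4 (0.0673).

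The K27M-P tumour, a single library used in no comparison, lay above all EV ctl, EV-PDGFRA and WT-AP libraries for the 6 genes that rose in K27M-AP. Those libraries are all preneoplastic, and no tumour here lacks the mutant histone. The histone and the tumour state therefore cannot be told apart in this contrast. The levels were 8.39 CPM for Tcf24 (0.455 to 1.17 in those libraries), 6.25 for Gm10567 (0.355 to 0.855), 6.29 for Plag1 (highest 0.197), 10.1 for AW551984 (0.0413 to 0.237), 23.3 for Zfp711 (2.07 to 14.6) and 9.33 for Bcl11a (0.207 to 2.35).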

How the results depend on the processing

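Among the alternatives below, the batch term, the libraries of 1 table alone, voom with weights, list tests with a library left out and the replicate block for K27M-APP against EV-PDGFRA were chosen only after the results were seen. DESeq2 size factors moved no count of called genes by over 1.5 times. DESeq2 called 64 genes for K27M-AP against WT-AP, 448 for WT-AP against EV ctl, 101 for EV-PDGFRA against EV ctl, 6 for K27M-APP against K27M-AP, 1371 for K27M-APP against EV-PDGFRA, 578 for K27M-AP T against K27M-AP, 62 for K27M-APP T against K27M-APP, 11 between the tumours, 6 for the Pdgfra interaction and 2 for the tumour interaction. Voom with weights gave 32 for K27M-AP against WT-AP, 2 for K27M-APP against K27M-AP, 5142 for K27M-APP against EV-PDGFRA, 115 for K27M-AP T against K27M-AP, 33 for K27M-APP T against K27M-APP and 2 between the tumours. The batch term gave 3 for K27M-AP against WT-AP, 2 for EV-PDGFRA against EV ctl and 20 for K27M-AP T against K27M-AP. For K27M-APP against EV-PDGFRA, all 23 libraries gave 171, only the compared groups 2264, the earlier table's libraries 653 and the replicate block 601. For K27M-AP T against K27M-AP, all 23 libraries gave 144, only the compared groups 0, each table alone 0, the block 29 and no filter 28. For K27M-AP against WT-AP, only the compared groups, each table alone and the block gave 0. Only the compared groups gave 13 for WT-AP against EV ctl and 1 for the Pdgfra interaction, the later table gave 2 for WT-AP against EV ctl, and the earlier table's libraries 1 between the tumours.

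Leaving out 1 library at a time gave 0 to 7 genes for K27M-AP against WT-AP, 31 to 350 for WT-AP against EV ctl, 0 to 9 for EV-PDGFRA against EV ctl, 44 to 162 for K27M-APP against EV-PDGFRA, 0 to 54 for K27M-AP T against K27M-AP, 0 to 1 between the tumours, 0 to 4 for the Pdgfra interaction, and 0 for the others. A group left with 1 library was assumed to vary like the others. List directions reversed in 5 cases: proliferation in K27M-AP against WT-AP in the earlier table (1.19e-05) and without K27M-AP 4 (0.135), proliferation in K27M-AP T against K27M-AP in the earlier table (0.671) and without K27M-AP 4 (0.483), and Hox in the same comparison in the later table (0.71). With 1 library left out at a time these proliferation lists had adjusted p of 3.66e-07 to 0.135 and 7.83e-06 to 0.483. Of the other list results 491 kept direction and side of the threshold and 164 weakened. Of named gene values 1166 kept their side of the threshold, 206 weakened, 5 strengthened and 0 changed direction with a call in either fit. Uncalled values among the 1166 could change direction. Trp53 did so in K27M-AP T against K27M-AP (log2 fold change 0.659, range -0.485 to 1.68). The cause was not tested. Whether replicate numbers pair the libraries was left unclear by correlations of same-numbered libraries' deviations from their group means. For K27M-AP against WT-AP these were -0.197, 0.46 and 0.579 for numbers 1, 2 and 3. Between the tumours they were 0.256, 0.379 and -0.0155 for numbers 1, 2 and 4. In the other comparisons with shared numbers they ran from -0.132 to 0.262. The earlier table alone had no EV ctl library and the later one no K27M-APP library, so those comparisons were not run. In simulations at these group sizes edgeR recovered 4 to 18% of genes changed 2-fold, so smaller changes were mostly out of reach.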

Other observations

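The tests of the overlap between comparisons below were chosen only after the results were seen. The 6 genes higher in K27M-AP than WT-AP (Plag1, Bcl11a, Zfp711, AW551984, Tcf24 and Gm10567) were all called higher in K27M-APP against EV-PDGFRA as well. Independent lists would share 0.0544 by chance, but these lists are not independent. The comparisons share no library, yet they share 1 fit and its estimate of each gene's spread. That can favour calls of the same genes, but it does not set their direction. With only the compared groups in the fit, K27M-AP against WT-AP gave 0 genes, while K27M-APP against EV-PDGFRA called 390 of its 392 genes again. In K27M-APP against EV-PDGFRA the log2 fold changes were 4.75 for Bcl11a, 3.20 for Zfp711, 2.61 for Tcf24 and 2.52 for Gm10567. Bcl11a was also lower in EV-PDGFRA than in EV ctl, though not called (log2 fold change -2.51, adjusted p = 0.115 by edgeR). Near zero in EV-PDGFRA, Plag1 stood at 8.90 ± 1.08 against 0.0426 ± 0.0414 CPM and AW551984 at 2.71 ± 0.633 against 0.0550 ± 0.0206. Chchd7, next to Plag1, stood at 16.7 ± 1.13 CPM in K27M-APP, 1.84 ± 0.418 in EV-PDGFRA, 28.6 ± 4.32 in K27M-AP T and 39.3 ± 14.8 in K27M-APP T. Across all genes the 2 comparisons correlated at 0.218. An effect of the mutant histone on these 6 genes is a hypothesis, since the 2 comparisons differ in more than the histone and other splits of the first gave as many genes.

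The K27M-P tumour (n = 1, no test) held 199.8 CPM of Pdgfra, 7.14 of Trp53, 291 of Atrx, 196 of H3f3a, 513 of H3f3b and 2.32 of Cdkn1a. The effects of tumour growth in the K27M-AP and K27M-APP backgrounds correlated at 0.367 across genes. The 5 genes called in K27M-AP tumours had log2 fold changes in K27M-APP tumours of 2.79 for Samd9l (unadjusted p = 9.52e-05), 3.64 for Ifi27 (6.39e-05), 3.64 for Lgals9 (0.00489), 1.05 for Nol3 (0.0101) and 2.79 for Lgi1 (0.000323).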
